A study of Homo sapiens with 9 samples.

How the data were processed

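Total RNA of 9 Hep3B samples was measured on Affymetrix human gene arrays, with 3 arrays each for untreated cells, nonsense siRNA and YAP siRNA. Per the labels, cells grew for 24 h, were transfected with Oligofectamine and were kept for another 24 h, RNA was extracted with a Nucleospin kit, and biotinylated cRNA was made by the standard Affymetrix protocol. The sample titles begin with HUH, while the cell line field and the descriptions name Hep3B, which was followed here; nothing in the values settled this. The values were log2 array signals as deposited by the authors; the unit was inferred from their range, and background correction, summarisation and normalization between arrays are not given in the sources used here. The array quartiles lay close together, so the arrays had been put on a common scale before deposit. No further scaling or pseudocount was applied.

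Probe sets were named from the array annotation supplied with the data. It listed 21214 probe sets, 19460 of them with 1 gene and 1754 with several, and 12083 were not listed. Probe sets with 1 gene gave 18417 genes, and for the 769 genes with several probe sets the one with the highest mean over the 9 arrays was used. Probe sets with several genes or none were left out of the comparisons. No genome positions were used.

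One linear model with a mean per group was fitted to all 9 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes, prior degrees of freedom 9.29), and the 3 pairwise differences were tested with limma's moderated test, two-sided. P-values were adjusted by Benjamini-Hochberg over all genes of a comparison, and a gene passed at an adjusted p under 0.05. Every adjusted p of a gene is from limma. The spread given with a group mean is the SD of 3 arrays, and SE is that of the fitted difference. YAP1 was also tested by exact permutation.

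The 22 gene lists, with 412 of 438 genes measured, the comparisons and the rule for named genes were fixed before the data were examined. Lists were tested with limma's camera at its preset correlation of 0.01, which compares a list with the other genes, and beside it with an estimated correlation and with fry, which tests whether a list's genes move on balance in one direction and does not compare them with other genes. Adjustment was over the 22 lists of a comparison. The rule named YAP1, the 12 largest rises and 12 largest falls after YAP siRNA against nonsense siRNA, the 8 and 8 largest for nonsense siRNA against untreated cells and the 5 and 5 largest for YAP siRNA against untreated cells. These had to pass, to have at least the median signal and to lie beyond the control arrays on all 3 arrays of the group. The rule added up to 4 members per list and comparison that passed, and 16 genes given whatever their result: CCN2, CCN1, ANKRD1, AXL, AMOTL2, JAG1, NOTCH2, HES1, FOXM1, CCNB1, WWTR1, TEAD4, ALB, AFP, CDKN1A and IFIT1.

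Alternatives were other scalings between arrays, filters on dim genes, the mean or all of a gene's probe sets, another variance model, only the 6 arrays of a comparison, stricter thresholds, other list tests, the replicate number as a block and leaving out each array in turn. After seeing the data, a covariate for small RNA levels, array weights and a fit without 3 arrays were added. The fit was tested on simulated data with 200 changed genes. Each gene was drawn independently, so the rates below leave out variation that genes share within an array. For YAP siRNA against nonsense siRNA it recovered 89.6% of changes of 0.3 and all of 0.5 or 1, with 6 false calls, and for YAP siRNA against untreated cells 79.1% and all, with 15. Figures were drawn with Python 3.11.15, matplotlib 3.10.9 and pandas 2.3.3. The number of arrays limits the precision.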

Results

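Total RNA of Hep3B cells, a human hepatocellular carcinoma line, was measured on 9 Affymetrix gene arrays. The arrays formed 3 groups of 3: untreated cells, cells transfected with a nonsense siRNA as a control, and cells transfected with an siRNA against YAP. A small interfering RNA (siRNA) lowers the level of the transcript it matches, and YAP, encoded by YAP1, is the transcriptional coactivator that the Hippo pathway restrains. RNA of the transfected cells was taken 24 h after transfection. Values were log2 array signals for 18417 genes, with array medians that differed by at most 0.06, and the number of arrays limits the precision. Pearson's r between arrays, taken across genes, which are not independent replicates, ranged from 0.981 to 0.993. The labels do not say that the 3 samples of a group came from separate cultures, so the spread behind each test is that between these samples.

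The YAP1 transcript was lower after YAP siRNA than in both control groups. Its probe set averaged 8.70 ± 0.08 (SD, n = 3) in untreated cells, 8.70 ± 0.05 (SD, n = 3) after nonsense siRNA and 7.51 ± 0.03 (SD, n = 3) after YAP siRNA. YAP1 fell by 1.18 on the log2 scale against nonsense siRNA (SE 0.0548, adjusted p = 4.34e-09), which left 44.0% of the control level, and it fell by 1.19 against untreated cells (adjusted p = 6.34e-09). The control groups did not differ detectably in YAP1 (adjusted p = 0.987). A two-sided exact permutation test gave p = 0.0119 for YAP siRNA against all 6 control arrays. Against the 3 nonsense siRNA arrays the exact permutation p was 0.1, the smallest that 3 arrays against 3 allow.

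**Figure D1:**
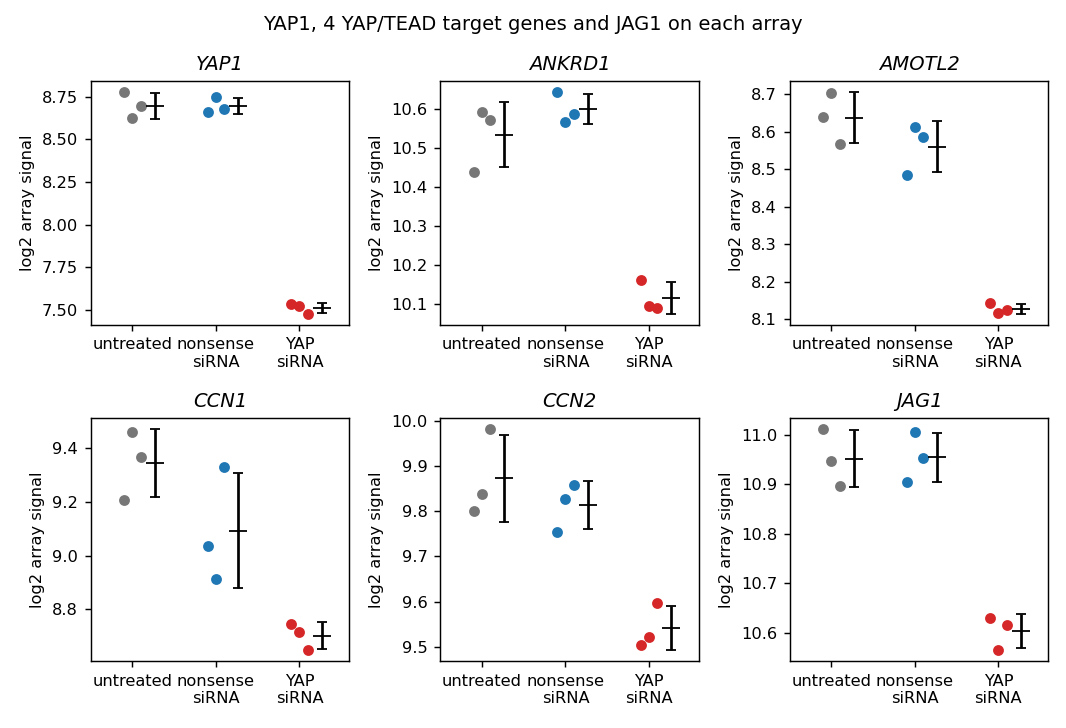
Log2 array signal of YAP1, of the YAP/TEAD target genes ANKRD1, AMOTL2, CCN1 and CCN2, and of the Notch ligand gene JAG1 on each of the 9 arrays; points are single arrays, and the dash and bar beside them give the mean and SD of each group of 3. The 3 YAP siRNA arrays lay below all 6 control arrays in each panel.

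The comparison of YAP siRNA with nonsense siRNA asked which transcripts differed when YAP1 was lowered in transfected cells. UHMK1, which encodes a serine/threonine kinase, fell by 1.47 on the log2 scale (SE 0.0571, adjusted p = 4.90e-10), and TNFRSF21, a death receptor gene of the tumour necrosis factor receptor family, fell by 1.39 (SE 0.0510, adjusted p = 3.99e-10). Both fell more than YAP1 in this comparison. MCL1, which encodes an anti-apoptotic protein, fell by 0.95 to 51.6% of the control level (SE 0.0535, adjusted p = 5.52e-08). The largest rise was that of STX12, an endosomal syntaxin gene, at 0.76 (SE 0.0694, adjusted p = 1.04e-05).

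Among the other named genes, LIN7C, a cell polarity scaffold gene, fell by 1.07, E2F5, of the E2F transcription factor family, fell by 0.96, and PLOD2, a collagen lysyl hydroxylase gene, fell by 0.91. PDCD4, which encodes an inhibitor of translation, fell by 0.89, FAM91A1 fell by 0.89 and TMTC3 fell by 0.81. LSM3, which encodes a part of splicing complexes, fell by 0.80, and the tight junction gene CLDN12 fell by 0.77. With all probe sets tested by limma, LSM3 did not pass (adjusted p = 0.0665). SOAT2, which esterifies cholesterol, rose by 0.53, GPAM, which begins glycerolipid synthesis, by 0.51, and the acyl-CoA synthetase gene ACSL5 by 0.46. AKR1D1, a steroid reductase gene of bile acid synthesis, rose by 0.49 and the glucuronosyltransferase gene UGT2B4 by 0.51. G3BP2, which encodes a stress granule protein, rose by 0.64, PLA2G7 by 0.56, TMT1A by 0.55, ZNF841 by 0.52, TNFRSF9 by 0.49 and PLEKHB2 by 0.48. In each of these genes the 3 YAP siRNA arrays lay beyond all 6 control arrays, as the rule for naming required.

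Known target genes of YAP and its TEAD partner factors shifted down as a list. Of 22 measured, 6 fell and 1 rose over all genes tested, and 9 fell and 1 rose when adjusted over the list alone (camera adjusted p = 2.93e-06, and adjusted p = 0.0307 with an estimated correlation). ANKRD1 fell by 0.48 (SE 0.0557, adjusted p = 8.84e-05), AMOTL2 fell by 0.43 (SE 0.0551, adjusted p = 0.000225) and CRIM1 fell by 0.35. CCN1 fell by 0.39 (adjusted p = 0.0178) and CCN2 fell by 0.27 (adjusted p = 0.0138). NT5E was the member that rose, by 0.24, and AXL did not pass, at -0.05 (adjusted p = 0.815). Without nonsense siRNA replicate 3 the adjusted p was 0.0731 for CCN1 and 0.0678 for CCN2, and CCN1 was also lost without YAP siRNA replicate 2 (0.0582) or 3 (0.0720). CCN2 was lost without YAP siRNA replicate 1 (0.0693) or 2 (0.0591) and with quantile normalization (0.0524). NT5E was lost in 7 of 9 fits that left out 1 array (highest adjusted p = 0.174, without YAP siRNA replicate 2). With all probe sets tested CCN1 (adjusted p = 0.160), CCN2 (0.0730) and NT5E (0.143) were lost. ANKRD1 (0.00589), AMOTL2 (0.00742) and CRIM1 (0.0348) still passed in that test.

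Hippo pathway components, a list that shares AMOTL2, LATS2 and PTPN14 with the target genes, also shifted down. Of 21 measured, 5 fell and 0 rose, and 7 fell and 0 rose when adjusted over the list alone (camera adjusted p = 1.36e-06, and adjusted p = 0.116 with an estimated correlation). TEAD1, which encodes a DNA-binding partner of YAP, fell by 0.42, MOB1B fell by 0.36 and WWC1 fell by 0.36; SAV1, outside the rule for naming and chosen after its values were seen, fell by 0.33. TEAD4, at -0.16 (adjusted p = 0.145), and the YAP paralog gene WWTR1, at 0.07 (adjusted p = 0.635), did not pass. In the Notch pathway list, JAG1, which encodes a Notch ligand, fell by 0.35 (SE 0.0533, adjusted p = 0.000989) and the protease gene ADAM17 fell by 0.37. The Notch list did not shift (2 of 25 fell and 0 rose, 3 fell and 2 rose when adjusted over the list alone, camera adjusted p = 0.822). NOTCH2, at -0.15 (adjusted p = 0.184), and the Notch target gene HES1, at -0.15 (adjusted p = 0.272), did not pass.

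The cell cycle lists shifted down by small amounts. Of 26 genes of DNA replication and the G1/S transition, 4 fell and 0 rose, and 8 fell and 0 rose when adjusted over the list alone (camera adjusted p = 7.32e-06, and adjusted p = 0.197 with an estimated correlation). POLA1, the catalytic subunit gene of DNA polymerase alpha, fell by 0.36, the histone mRNA-binding protein gene SLBP fell by 0.32, RRM2 fell by 0.32 and CCNE1 fell by 0.26. Of 25 mitotic and G2/M genes only KIF23 passed over all genes, and it fell by 0.23; 1 fell when adjusted over the list alone (camera adjusted p = 0.000215, and adjusted p = 0.493 with an estimated correlation). Of 25 genes of a chromosomal instability signature, which shares members with both cell cycle lists, RAD51AP1 fell by 0.33, and 2 fell when adjusted over the list alone (camera adjusted p = 0.00128, and adjusted p = 0.330 with an estimated correlation). FOXM1, at -0.05 (adjusted p = 0.781), and CCNB1, at -0.05 (adjusted p = 0.840), did not pass. With 1 array left out, CCNE1 was lost in 6 of 9 fits (highest adjusted p = 0.172, without YAP siRNA replicate 3), KIF23 in 6 (0.172, without nonsense siRNA replicate 3), RAD51AP1 in 3 (0.0817, without nonsense siRNA replicate 1) and RRM2 in 1 (0.0509, without nonsense siRNA replicate 1). The G2/M and chromosomal instability lists were lost without YAP siRNA replicate 3 (adjusted p = 0.0583 and 0.0583) and by fry (0.239 and 0.148). Against untreated cells the 3 lists did not shift: the mean was -0.02 for G1/S (camera adjusted p = 0.838), 0.02 for G2/M (0.550) and 0.01 for chromosomal instability (0.892). As lists they thus shifted down against 1 of the 2 controls only. After YAP siRNA, RAD51AP1 differed from untreated cells by -0.01, CCNE1 by -0.04 and KIF23 by -0.07, and none of them passed. Single G1/S genes fell against untreated cells as well: SLBP by 0.27, POLA1 by 0.25 and RRM2 by 0.25 (4 lower and 1 higher when adjusted over the list alone). Of these POLA1 was lost in 5 of 9 fits with 1 array left out (highest adjusted p = 0.123, without untreated replicate 1) and RRM2 in 6 (0.187, without YAP siRNA replicate 2). All 3 lists were higher after nonsense siRNA than in untreated cells at the preset correlation, but not with an estimated one (adjusted p = 0.429, 0.488 and 0.429) or by fry (0.118, 0.176 and 0.176). With the small RNA level as a covariate, chosen after seeing the data, the G2/M mean after YAP siRNA against nonsense siRNA went from -0.09 to -0.06 (adjusted p = 0.0131), and the other 7 lists that shifted in this comparison passed at 0.0131 or less.

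Cholesterol synthesis and the RNA interference machinery shifted down as well. Of 16 cholesterol synthesis genes, SREBF2, which encodes a sterol-responsive transcription factor, fell by 0.24 and INSIG1, whose protein holds that factor in the endoplasmic reticulum, fell by 0.21. Over all genes 2 fell and 0 rose, and 6 fell and 0 rose when adjusted over the list alone (camera adjusted p = 4.16e-05, and adjusted p = 0.0799 with an estimated correlation). Of 13 RNA interference genes, the Argonaute genes AGO2 and AGO4 were the 2 that passed: AGO2 fell by 0.41 and AGO4 fell by 0.32, and 4 fell and 1 rose when adjusted over the list alone (camera adjusted p = 0.00172, and adjusted p = 0.280 with an estimated correlation). Interferon-stimulated genes shifted up. The chemokine gene CXCL10 rose by 0.32, the only one of 25 to pass over all genes and when adjusted over the list alone (camera adjusted p = 0.00376, and adjusted p = 0.251 with an estimated correlation), and IFIT1 did not pass, at 0.16 (adjusted p = 0.160). SREBF2 was lost without nonsense siRNA replicate 1 (adjusted p = 0.104) or YAP siRNA replicate 1 (0.0982), and INSIG1 in 6 of 9 such fits (highest adjusted p = 0.159, without nonsense siRNA replicate 1). With only the genes above the 50th percentile of signal, the interferon (adjusted p = 0.242) and RNA interference lists (adjusted p = 0.220) did not pass. CXCL10 and IFIT1 were dim, with mean signals of 6.47 and 5.90 where the median over genes was 7.31. Against untreated cells none of the 3 lists shifted by camera (adjusted p = 0.609 for cholesterol synthesis, 0.930 for RNA interference and 0.0740 for interferon), though with the small RNA covariate the interferon list passed (0.0381). The first 2 were higher after nonsense siRNA than in untreated cells at the preset correlation, but not with an estimated one (adjusted p = 0.429 for each) or by fry (0.0932 for each). After YAP siRNA, AGO2 differed from untreated cells by -0.13 and INSIG1 by -0.10, and neither passed.

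The remaining lists did not shift by camera. Of 28 hepatocyte genes, AHSG rose by 0.29 and HPX by 0.25, while FGA fell by 0.24 and FOXA1 fell by 0.22 (3 higher and 2 lower when adjusted over the list alone, adjusted p = 0.710). ALB, the albumin gene, at -0.06 (adjusted p = 0.746), and AFP, the alpha-fetoprotein gene, at -0.04 (adjusted p = 0.812), did not pass. Of 14 fetal liver and progenitor genes, IGF2BP3 fell by 0.39 and CD24 fell by 0.41 (3 lower when adjusted over the list alone, adjusted p = 0.237). Of 16 p53 target genes, TP53INP1 fell by 0.53, while TNFRSF10B rose by 0.22 and TP53I3 by 0.20 (2 higher and 3 lower when adjusted over the list alone, adjusted p = 0.237). CDKN1A did not pass, at -0.02 (adjusted p = 0.946), and its mean signal of 6.91 lay under the median of 7.31 over genes. The activity of p53 was not measured, so changes in this list are not a readout of it. Of 18 unfolded protein and integrated stress response genes, DNAJC3 fell by 0.28 and ATF4 fell by 0.21 (2 lower when adjusted over the list alone, adjusted p = 0.237). With 1 array left out, the highest adjusted p was 0.0904 for AHSG (without YAP siRNA replicate 1), 0.146 for FOXA1 (without YAP siRNA replicate 3), 0.188 for FGA, 0.0855 for TNFRSF10B and 0.137 for ATF4 (without nonsense siRNA replicate 3), and 0.180 for HPX, 0.213 for CD24 and 0.211 for TP53I3 (without nonsense siRNA replicate 1).

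Of 17 hypoxia and glycolysis genes, NDRG1 fell by 0.38 (1 higher and 1 lower when adjusted over the list alone, adjusted p = 0.581), and of 15 immediate early genes the phosphatase gene DUSP1 fell by 0.40 (1 lower when adjusted over the list alone, adjusted p = 0.565). Of 16 NF-kB and inflammatory genes ICAM1 rose by 0.29 (1 higher when adjusted over the list alone, adjusted p = 0.394). Of 19 fatty acid and lipid droplet genes DGAT1 rose by 0.23 and ACSL4 fell by 0.26 (3 higher and 2 lower when adjusted over the list alone, adjusted p = 0.822). Of 17 actin cytoskeleton genes TPM4 rose by 0.54 and TPM1 fell by 0.26 (1 higher and 1 lower when adjusted over the list alone, adjusted p = 0.822). Of 21 extracellular matrix and adhesion genes ITGA2 rose by 0.24 (4 higher and 2 lower when adjusted over the list alone, adjusted p = 0.860), and of 18 ribosome biogenesis genes NOLC1 rose by 0.48 (3 higher when adjusted over the list alone, adjusted p = 0.822). TPM4 and NOLC1 differed by -0.10 and 0.02 between YAP siRNA and untreated cells, and neither passed there. After nonsense siRNA they were lower than in untreated cells, by 0.64 and 0.45. Among 13 stromal and endothelial markers COL1A2 rose by 0.43 and PDGFRA by 0.35 (2 higher when adjusted over the list alone, adjusted p = 0.261). Of 13 leukocyte markers 0 passed by limma over all genes or when adjusted over the list alone, and 0 had an unadjusted p under 0.05 (camera adjusted p = 0.390). Median, mean and test differed in sign in 5 lists, of which 0 had shifted: Notch, actin, extracellular matrix, immediate early and ribosome biogenesis. Without nonsense siRNA replicate 1 the adjusted p was 0.0817 for ICAM1, 0.113 for DGAT1, 0.0771 for ACSL4 and 0.140 for TPM1, and for ITGA2 it was 0.0910 without YAP siRNA replicate 2.

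**Figure D2:**
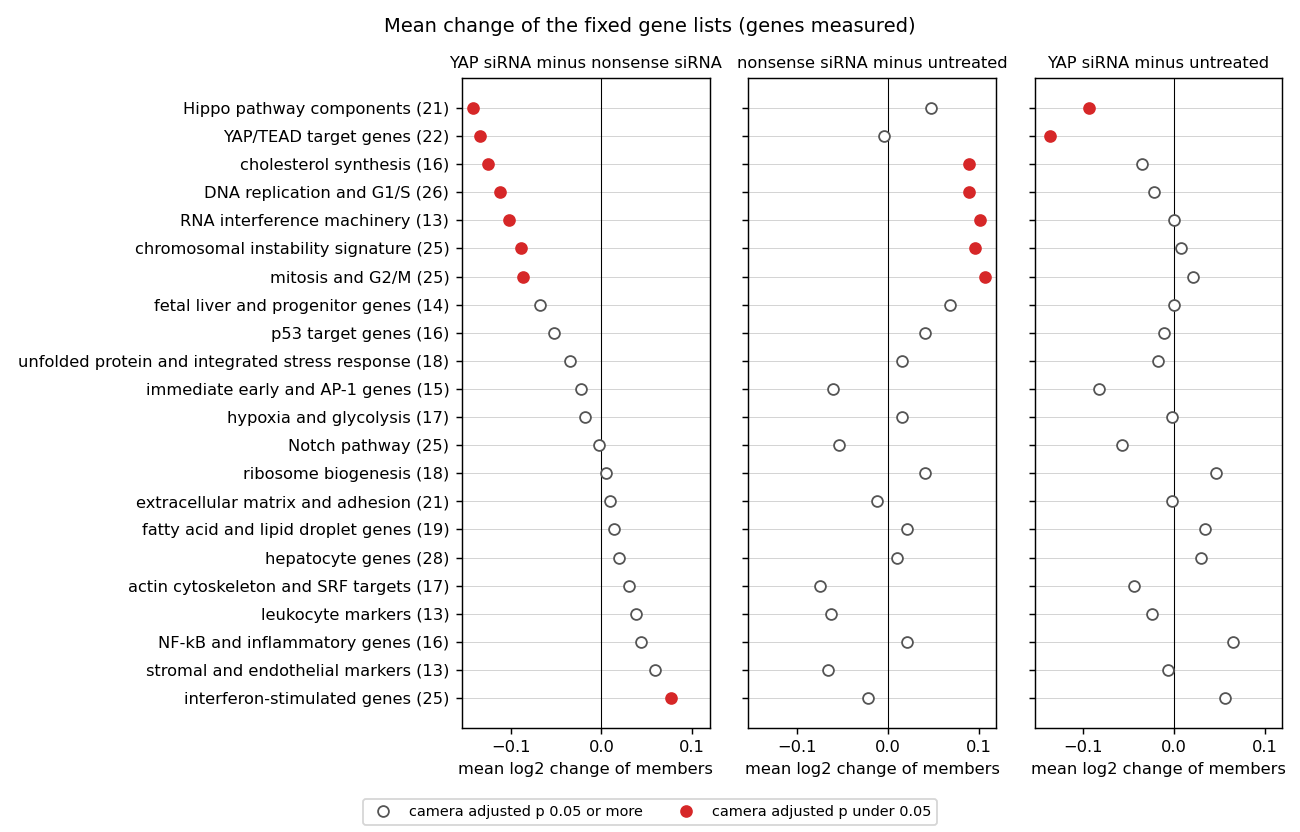
Mean log2 change of the measured members of each of the 22 gene lists in the 3 comparisons, with the number of measured genes in brackets; filled points passed camera at an adjusted p under 0.05 with the preset correlation. Filled points number 8 for YAP siRNA against nonsense siRNA, 5 for nonsense siRNA against untreated cells and 2 for YAP siRNA against untreated cells.

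Over all 18417 genes, 834 differed between YAP siRNA and nonsense siRNA, 354 higher and 480 lower. UHMK1, TNFRSF21, YAP1 and LIN7C fell by at least 1 on the log2 scale and no gene rose by as much, and at a size of at least 0.5 there were 70 lower and 11 higher. Quantile normalization gave 460 higher and 408 lower genes, and a test of all probe sets gave 351. The count was 426 without nonsense siRNA replicate 1, 497 without nonsense siRNA replicate 3, 534 without YAP siRNA replicate 1, 521 without YAP siRNA replicate 2, and 1287 without nonsense siRNA replicate 2, YAP siRNA replicate 3 and untreated replicate 3 together.

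The comparison of nonsense siRNA with untreated cells asked which transcripts differed between cells transfected with the control siRNA and untransfected cells. OGFR, the opioid growth factor receptor gene, fell by 0.60 (SE 0.0558, adjusted p = 0.000277) and TPM4, a tropomyosin gene, fell by 0.64 (SE 0.0840, adjusted p = 0.00343). G3BP2 fell by 0.45 (SE 0.0519, adjusted p = 0.00166) and UHMK1 rose by 0.46 (SE 0.0571, adjusted p = 0.00225). MT1M and MT1G, which encode metal-binding metallothioneins, rose by 0.83 (adjusted p = 0.0112) and 0.56 (adjusted p = 0.0181). Their paralogs share sequence, so the probe signal cannot be given to one gene with certainty.

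Other genes that fell were ZNF616 by 0.50, HABP4 by 0.49, the lysine methyltransferase gene SETD7 by 0.47, the nucleolar protein gene NOLC1 by 0.45 and PCNX3 by 0.45. A dimmer probe set of ZNF616 differed by 0.01. Genes that rose were PCBP1 by 0.53, IPMK by 0.49, the ribosomal protein gene RPL31 by 0.48, the histone gene H2BC7 by 0.47 and PRTG by 0.45; RPL31 and H2BC7 have close copies in the genome, which leaves their signal uncertain too. OGFR averaged 8.68 ± 0.02 (SD, n = 3) in untreated cells, 8.07 ± 0.09 (SD, n = 3) after nonsense siRNA and 8.59 ± 0.05 (SD, n = 3) after YAP siRNA. Without nonsense siRNA replicate 1 the adjusted p was 0.0971 for MT1G, 0.198 for PCBP1, 0.206 for IPMK, 0.261 for RPL31, 0.215 for H2BC7 and 0.0540 for PRTG. It was 0.0631 for MT1M and 0.0631 for NOLC1 without untreated replicate 1, and 0.0739 for SETD7 without nonsense siRNA replicate 3.

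**Figure D3:**
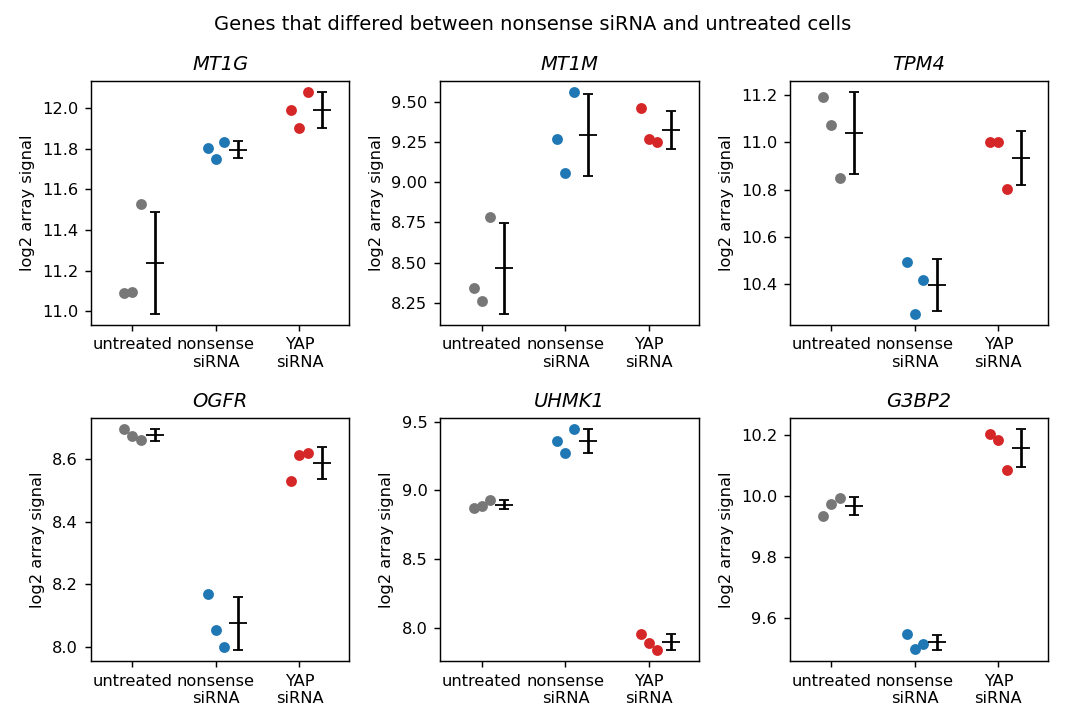
Log2 array signal of 6 genes that differed between nonsense siRNA and untreated cells, on each of the 9 arrays; points are single arrays, and the dash and bar beside them give the mean and SD of each group of 3. TPM4, OGFR and G3BP2 were lower after nonsense siRNA than in untreated cells, and MT1G, MT1M and UHMK1 were higher.

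Among the lists, 5 shifted up between nonsense siRNA and untreated cells by camera with its preset correlation. They were mitosis and G2/M (mean 0.11, adjusted p = 1.92e-05, and adjusted p = 0.488 with an estimated correlation), DNA replication and G1/S (mean 0.09, 0.000176 and 0.429), chromosomal instability (mean 0.10, 0.00122 and 0.429), cholesterol synthesis (mean 0.09, 0.00292 and 0.429) and RNA interference machinery (mean 0.10, 0.00199 and 0.429). With the small RNA covariate the G2/M mean was 0.06 (adjusted p = 0.0116). With an estimated correlation 0 lists passed (1 at an unadjusted p under 0.05), and 0 by fry (5). In the RNA interference list TNRC6A rose by 0.39 and AGO2 by 0.27, and 3 rose when adjusted over the list alone. In the other 4 lists 0 genes passed by limma over all genes, and 4 mitotic, 5 replication, 6 chromosomal instability and 1 cholesterol synthesis genes rose when adjusted over the list alone, with 9, 6, 8 and 5 at an unadjusted p under 0.05. In the lists that did not shift, TPM4, NOLC1 and the stress response gene TRIB3, which fell by 0.33, were the genes that passed. Median, mean and test differed in sign in 4 lists, none of which had shifted by camera. Without nonsense siRNA replicate 1 the adjusted p was 0.160 for AGO2, 0.107 for TNRC6A and 0.172 for TRIB3, and the RNA interference list was lost without untreated replicate 3 (adjusted p = 0.0583). With quantile normalization the cholesterol (adjusted p = 0.156) and chromosomal instability lists (adjusted p = 0.132) were lost, and with only the genes above the 50th percentile of signal these and the RNA interference list were lost (adjusted p = 0.0832 for each). The RNA interference list was also lost without nonsense siRNA replicate 2, YAP siRNA replicate 3 and untreated replicate 3 together (adjusted p = 0.152).

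In all, 113 genes differed between nonsense siRNA and untreated cells, 62 higher and 51 lower, the metallothionein genes MT1M and MT1G among the first and OGFR and TPM4 among the second. Small nucleolar and Cajal body RNA genes had medians of 6.94, 6.80 and 6.93 on the nonsense siRNA arrays and 6.80, 6.88 and 6.70 on the untreated arrays. Median centring gave 32 higher and 17 lower genes, quantile normalization gave 70 higher and 79 lower, the 6 arrays alone gave 67 genes, and a test of all probe sets by limma gave 0 (4645 probe sets at an unadjusted p under 0.05). The count was 1470 without nonsense siRNA replicate 2, 229 without YAP siRNA replicate 3 and 2319 without these and untreated replicate 3 together. It was 11 and 17 without nonsense siRNA replicates 1 and 3 (higher and lower: 2 and 9, and 4 and 13), 17, 16 and 28 without untreated replicates 1, 2 and 3, and 54 and 64 without YAP siRNA replicates 1 and 2.

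Compared with untreated cells, TNFRSF21 fell by 1.36 after YAP siRNA (SE 0.0510, adjusted p = 5.80e-10), UHMK1 fell by 1.00 (adjusted p = 9.16e-08) and MCL1 fell by 0.78 (adjusted p = 9.53e-07). GPC6, which encodes a cell-surface glypican, fell by 0.83 (adjusted p = 7.14e-06). AKR1D1 rose by 0.68 (adjusted p = 1.46e-05) and UGT2B4 by 0.74 (adjusted p = 7.45e-05). MT1G rose by 0.75 (adjusted p = 0.000298), MT2A by 0.62 (adjusted p = 0.000968) and the chemokine gene CCL20 by 0.73 (adjusted p = 0.00265). Against nonsense siRNA these 3 did not pass, at 0.20, 0.19 and 0.34 (adjusted p = 0.321, 0.304 and 0.154).

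The YAP/TEAD target genes shifted down against untreated cells too (6 of 22 fell and 1 rose, 9 fell and 1 rose when adjusted over the list alone, camera adjusted p = 0.000167, and adjusted p = 0.0621 with an estimated correlation). CCN1 fell by 0.64 (adjusted p = 0.000727), AMOTL2 fell by 0.51, ANKRD1 fell by 0.42 and CCN2 fell by 0.33, while NT5E rose by 0.39. Hippo pathway components shifted down (4 of 21 fell and 0 rose, 7 fell when adjusted over the list alone, camera adjusted p = 0.0386, and adjusted p = 0.477 with an estimated correlation). Besides AMOTL2, TEAD2 fell by 0.42, WWC1 fell by 0.38 and TEAD1 fell by 0.24. Among the lists that did not shift, JAG1 fell by 0.35 (adjusted p = 0.00149), NDRG1 fell by 0.41, DUSP1 fell by 0.37, TP53INP1 fell by 0.51 and SREBF2 fell by 0.31, while CXCL10 rose by 0.48. In the RNA interference list TNRC6A rose by 0.36 and AGO4 fell by 0.21, which was lost in 7 of 9 fits with 1 array left out (highest adjusted p = 0.193, without YAP siRNA replicate 1). Genes higher and lower over all genes were 1 and 3 in the stress response list, 2 and 2 in lipid, 2 and 1 in NF-kB, 0 and 2 in Notch, 0 and 3 in G1/S, 1 and 1 in p53 and 1 and 1 in extracellular matrix. They were 1 and 0 in hepatocyte, 1 and 0 in interferon, 1 and 0 in stromal, 0 and 1 in cholesterol, 0 and 1 in hypoxia and 0 and 1 in immediate early genes. In the fetal liver, G2/M, chromosomal instability, ribosome biogenesis, leukocyte and actin lists 0 passed by limma (5, 2, 2, 1, 1 and 0 at an unadjusted p under 0.05). Median, mean and test differed in sign in 5 lists, none of which had shifted by camera. The Hippo list was lost without untreated replicate 1 (adjusted p = 0.0781), untreated replicate 2 (0.0781) or YAP siRNA replicate 3 (0.271), and with all probe sets tested (0.0531). It was also lost with array weights (0.0880), by fry (0.0850) and with the replicate number as a block. Without nonsense siRNA replicate 2, YAP siRNA replicate 3 and untreated replicate 3 together the Hippo list was lost too (0.137). TEAD1 was lost in 6 of 9 fits with 1 array left out (highest adjusted p = 0.151, without untreated replicate 2).

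In all, 569 genes differed between YAP siRNA and untreated cells, 300 higher and 269 lower, with TNFRSF21, YAP1 and UHMK1 the 3 that fell by at least 1 on the log2 scale. More genes were lower than higher without YAP siRNA replicate 1 or 2 (higher and lower: 123 and 158, and 114 and 165) or untreated replicate 1 (140 and 159). Median centring gave 350 higher and 181 lower genes, and a test of all probe sets gave 183. The count was 299 without untreated replicate 1, 347 without untreated replicate 2, 281 without YAP siRNA replicate 1, 279 without YAP siRNA replicate 2, and 1560 without untreated replicate 3, nonsense siRNA replicate 2 and YAP siRNA replicate 3 together.

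Genes that differed from both controls in the same direction numbered 332. Of these 128 were higher, AKR1D1, UGT2B4 and STX12 among them, and 204 were lower, among them TNFRSF21, UHMK1, MCL1, AMOTL2 and JAG1. Independent lists of these sizes would share 12.8 genes, and 0 genes passed limma in opposite directions. The log2 changes of the comparisons had Pearson's r = 0.513 across genes, which are not independent replicates, and simulated arrays without any effect gave 0.50, since the YAP siRNA arrays are shared. The covariance was 0.00615 against a simulated 0.00203, a difference of 0.00413. As 3 arrays could not be split into parts of at least 2, the part of the overlap that comes from the shared arrays was not measured. Over all genes 58.0% had the same sign in both comparisons, against a simulated 66.7%. The simulated arrays drew each gene independently and without array-wide offsets. The real medians over genes were 0.0108 against nonsense siRNA and -0.0138 against untreated cells, so no conclusion is drawn from this gap. Of the 834 genes that differed from nonsense siRNA, 61 also differed between nonsense siRNA and untreated cells in the opposite direction, OGFR, TPM4 and G3BP2 included. The nonsense siRNA arrays enter these comparisons with opposite signs, which favours such pairs: r was -0.530 across genes and -0.501 in arrays simulated without any effect. The count of genes that differed from both controls was 190 without YAP siRNA replicate 1, 190 without YAP siRNA replicate 2 and 217 without untreated replicate 2, and 129 with all probe sets tested.

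**Figure D4:**
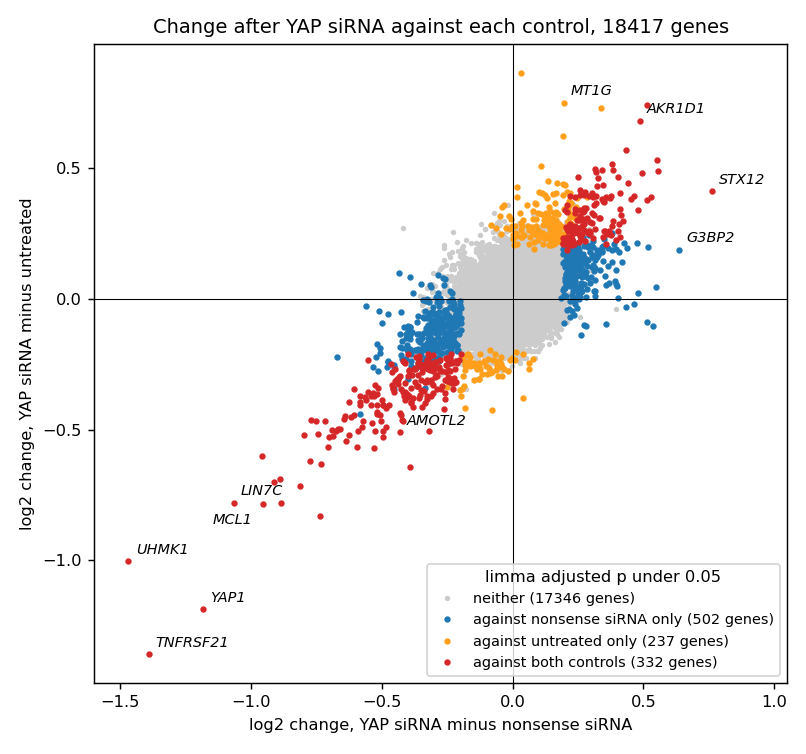
Log2 change of each gene after YAP siRNA against untreated cells (vertical axis) and against nonsense siRNA (horizontal axis); each point is a gene, and colours mark those that passed limma at an adjusted p under 0.05 against both controls (332), one of them or neither. TNFRSF21, UHMK1 and YAP1 lie farthest to the lower left.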

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

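The tests of the nonsense siRNA response, of the small RNA covariate and of the large falls were chosen after the results were seen, and those of the nonsense siRNA response replaced earlier ones whose choice of genes fixed their outcome. Probe sets outside the gene comparisons drew attention because some of them differed too. Of 12083 probe sets without a gene in the annotation, 42 differed between YAP siRNA and nonsense siRNA (17 higher, 25 lower) and 16 between YAP siRNA and untreated cells (9 higher, 7 lower) by limma over all probe sets. Between nonsense siRNA and untreated cells 0 did, with 1161 at an unadjusted p under 0.05. Of 1754 probe sets with several genes, 13, 2 and 0 differed in the same order, with 265 at an unadjusted p under 0.05 in the last.

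The first pattern is the set of 834 genes that differed between YAP siRNA and nonsense siRNA. A response to the nonsense siRNA alone, without any effect of the YAP siRNA, is argued against as the whole cause, since 39.8% of them (332) also passed against untreated cells in the same direction. For the other 502 genes the median ratio of the change against untreated cells to that against nonsense siRNA was 0.426 (quartiles 0.259 and 0.592), which is low by their selection, so this explanation stays open for them. The small RNA level was used as a covariate for an array-wide difference in labelling or RNA quality. With it the changes of the 834 genes kept a median of 0.965 of their size (quartiles 0.913 and 1.02). These genes were called without the covariate and so had little spread within groups, from which its slope is estimated. Their selection thus favours a ratio near 1, and this test cannot decide on that explanation. In 100 splits of the 9 arrays, 1, the real one, gave as many genes that differed from both controls (332, and at most 5 in the others). This argues against a chance split of these arrays for that count. The labels do not say that the samples of a group came from separate cultures. Chance differences between single cultures therefore stay open.

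The second pattern is the set of 113 genes and 5 lists that differed between nonsense siRNA and untreated cells. With the small RNA covariate the changes of the 113 genes kept a median of 0.921 of their size (quartiles 0.839 and 1.01). These genes too were called without the covariate, and their selection favours a ratio near 1. An array-wide difference tracked by small RNA levels thus stays open, as does one along the main axis of variation within groups. The change across genes correlated with that axis (Pearson's r = 0.621). Only 23 of the 113 genes still passed with the covariate. The median size of the 113 changes went from 0.32 (SD 0.0931) to 0.29 (SD 0.105) and the median SE from 0.0590 to 0.0616. The cause of the lost calls was not tested. The means of the 5 lists kept on average 0.711 of their size (from 0.523 for mitosis and G2/M to 0.881 for cholesterol synthesis), and all 5 still passed camera at its preset correlation, which leaves that explanation open as part of the lists' shift. A biological response, to transfection or to the nonsense siRNA itself, stays open. The YAP siRNA cells were transfected too. Of the 113 genes, 21 also differed between YAP siRNA and untreated cells in the same direction. In the opposite direction, 61 differed between YAP siRNA and nonsense siRNA. Each count rests on arrays shared with the comparison that gave the 113 genes, which favours such pairs. The counts thus do not separate transfection from the nonsense siRNA.

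The third pattern is the size of the falls after YAP siRNA, with UHMK1 and TNFRSF21 falling more than YAP1 against nonsense siRNA. Against untreated cells TNFRSF21 fell by 1.36, still more than YAP1 at 1.19, while UHMK1 fell by 1.00. After nonsense siRNA UHMK1 was 0.46 higher than in untreated cells, and TNFRSF21 was 0.03 higher. Among the 69 genes other than YAP1 that fell by at least 0.5 against nonsense siRNA, 0 belonged to the list of 22 known YAP/TEAD target genes, where 0.0824 would be expected by chance, so this test could not decide for or against lower activity of the known YAP/TEAD targets as a cause of the largest falls. Off-target effects of the YAP siRNA may contribute to these falls, and the count of 0 does not test this; siRNA and 3' UTR sequences were not used here. A biological effect of lower YAP on genes outside the list stays open as well.

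For each comparison of 3 arrays with 3, the 10 splits are too few for a share under 0.05. The gene counts were 834 (1 split as large, the highest other 2), 113 (1, highest other 0) and 569 (1, highest other 0) for YAP siRNA against nonsense siRNA, nonsense siRNA against untreated cells and YAP siRNA against untreated cells. The list counts were 8 (2 splits, highest other 8), 5 (3 splits, highest other 6) and 2 (5 splits, highest other 7). Other splits of the same arrays thus gave as many shifted lists in each comparison, so chance stays open for the 3 list counts. Within groups, 38.2% of the residual variance lay on 1 axis with nonsense siRNA replicate 2 (-0.55), YAP siRNA replicate 3 (-0.53) and untreated replicate 3 (-0.25) at one end. Across genes, which are not independent replicates, Pearson's r between this axis and the log2 change was -0.297, 0.621 and 0.317 for the 3 comparisons in the order above, and the value expected without an effect was not computed.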

How the results depend on the processing

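The small RNA covariate, the array weights and the fit without 3 arrays (nonsense siRNA replicate 2, YAP siRNA replicate 3 and untreated replicate 3) were chosen after seeing the data. Single genes were followed only if named, and lists only if they had shifted in the main fit. None of these changed direction where it had passed. The direction of the other called genes was not followed. Of the gene results 3729 kept their side of the threshold, 435 lost it and 15 gained it. With all probe sets tested 123 gene results kept it and 77 lost it. Of the list results 305 kept it and 40 lost it. Of the counts and the YAP1 change 126 values stayed the same and 56 did not. For this a count had to stay within 1.5 times, and YAP1 had to keep its direction and its side of the threshold. The following give YAP siRNA against nonsense siRNA, nonsense siRNA against untreated cells, YAP siRNA against untreated cells and both controls, in this order, as counts of genes. All probe sets tested gave 351, 0, 183 and 129; this changed the number of tests and also the prior degrees of freedom of the variance (2.47 against 9.29). An adjusted p under 0.01 gave 396, 11, 250 and 153, and a log2 change of at least 1 gave 4, 0, 3 and 3, as stricter thresholds must lower them. Array weights gave 2404, 2620, 1759 and 742, and the fit without 3 arrays 1287, 2319 and 1560 for the first 3. Nonsense siRNA against untreated cells gave 49 genes with median centring, 67 with only the 6 arrays compared, 65 with the replicate block and 24 with the small RNA covariate; the replicate numbers did not pair the samples (3 of 9 pairs of equal number correlated above 0.1). Leaving out 1 array gave 426 to 1231, 11 to 1470, 279 to 775 and 190 to 364 genes. The balance of higher and lower genes turned, however. For YAP siRNA against nonsense siRNA it was 354 and 480, and 460 and 408 with quantile normalization. For nonsense siRNA against untreated cells it was 62 and 51, and 70 and 79 with quantile normalization, 3 and 8 at an adjusted p under 0.01, 9 and 15 with the small RNA covariate, and lower genes were also more numerous without nonsense siRNA replicate 1 or 3 or any 1 untreated array. For YAP siRNA against untreated cells it was 300 and 269, and 122 and 128 at an adjusted p under 0.01, 84 and 99 with all probe sets tested, and turned also without YAP siRNA replicate 1 or 2 or untreated replicate 1. Lists shifted with an estimated correlation numbered 1, 0 and 0. For nonsense siRNA against untreated cells fry gave 0 lists and the genes above the 50th percentile of signal gave 3. For YAP siRNA against untreated cells fry, array weights, the replicate block and the fit without 3 arrays gave 1 list each, the YAP/TEAD targets, with the Hippo list lost, and quantile normalization gave 4. Leaving out 1 array gave 6 to 9, 5 to 7 and 1 to 4 lists, and a YAP1 change of -1.20 to -1.16. Apart from the stricter thresholds, the cause of these differences was not tested, also where arrays were left out. Pseudocounts were not run, because the values were already log2. Signal over background could not be assessed, since background values were not used here.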

Other observations

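Gene families formed from shared symbol stems, 331 in all, were tested with camera after the data were seen. The MT1 and MT2 family has 13 measured metallothionein genes and pseudogenes that share sequence; MT1DP, MT1IP, MT1JP and MT1P3 are pseudogenes, of which MT1DP, MT1IP and MT1JP are among the 10 and MT1JP is among the 4 below. Against untreated cells 10 passed after YAP siRNA (median 0.41, adjusted p = 1.95e-17, unadjusted p = 0.0188 by limma's camera with an estimated correlation) and 4 after nonsense siRNA (median 0.25, adjusted p = 1.65e-09, unadjusted p = 0.0527 by limma's camera with an estimated correlation). Between the siRNAs 0 passed by limma, with a median of 0.14 (camera adjusted p = 0.0295, unadjusted p = 0.273 with an estimated correlation). Families that shifted numbered 6 for YAP siRNA against nonsense siRNA, 24 for nonsense siRNA against untreated cells and 3 for YAP siRNA against untreated cells. With the small RNA covariate, chosen after seeing the data, 0, 2 and 2 of these passed camera in the same order.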
